A study of Homo sapiens with 2 samples.

How the data were processed

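Small RNA was sequenced from 2 samples of FaDu, a squamous cell carcinoma line of the hypopharynx (written FadU in the labels): parental cells and cells expanded as spheres, with 1 library per group. Per the labels' protocols, libraries were built from 1 µg of total RNA with the TruSeq small RNA kit and size fractionation. Per the labels' protocols, parental cells grew in RPMI-1640 with 10% fetal bovine serum, and spheres in DMEM-F12 with N2 supplement, 10 ng/ml bFGF and 10 ng/ml EGF. Medium, serum and growth form therefore changed together with the group. The submitters' processing notes name the hg19 genome build. The aligner, the counting tool, the miRNA annotation release and the treatment of reads that match several miRNA genes are not given in the sources used here.

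Each deposited file gives 1 RPKM value (reads per kilobase and 1000000 reads, computed by the authors, per the file headers) for each of 2038 mature miRNA names, with no raw counts. No name occurs more than once in a file. The analysis was planned for counts, with a branch for normalized values. Since the files hold RPKM, that branch was used, without a count model. RPKM summed to 26530004 in the parental library and 5509071 in the sphere library, so the reads the authors divided by are not the miRNA total.

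The low values allow an estimate of the reads behind the RPKM of each library. In both columns they fall on steps that stand to each other as the inverse of mature lengths near 22 nt. The commonest value, taken as 1 read on 22 nt, was 5.84 RPKM in the parental and 8.07 RPKM in the sphere library, which puts 7782765 and 5630047 reads behind the RPKM of the 2 libraries. Of the values between 0.9 and 5 such steps, 57.6% of 278 (parental) and 62.3% of 231 (spheres) were whole reads on 20 to 24 nt within a relative tolerance of 0.0001. Among about 1000 other depths tried per library, the highest shares were 29.5% and 12.1%. These depths were drawn at random, while the chosen one was set from the commonest of the same values. The check therefore shows that the values fall on steps. It cannot show that the commonest step is 1 read on 22 nt, and not another length or number of reads. Another 138 and 136 values lay below the 1-read value, so under this estimate the values include fractions of reads. Reads per miRNA were therefore estimated as RPKM divided by the 1-read value, which ignores differences in mature length. They serve for read numbers, intervals, floors, differences between pairs of miRNAs and the simulation, not for the log2 folds. A value of 0 allows up to 3 reads, or 17.5 RPKM in the parental and 24.2 RPKM in the sphere library.

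For the comparison, each column was rescaled to sum to 1000000 ("rescaled RPKM"), because the planned scaling was the miRNA total. A read is then worth 0.22 in the parental and 1.47 in the sphere library. The log2 fold is that of (rescaled RPKM + 0.5) in spheres over parental, which understates changes of low miRNAs. A miRNA counted as measured at a mean of at least 10 rescaled RPKM over both libraries, which left 269. Higher or lower means a fold of at least 2. With 1 library per group no test between conditions is possible and no p-value is given. The 95% intervals of folds are exact (Clopper-Pearson) intervals of the ratio of estimated reads. Those of differences in log2 fold between 2 miRNAs are symmetric normal approximations. Both kinds compare these 2 libraries, not the conditions, and cover counting error only, since PCR copies are not independent molecules.

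27 lists of miRNAs were fixed before the data were examined: let-7, miR-200, miR-17-92, miR-34, miR-15/16, miR-23/27/24, miR-29, miR-30, miR-181, miR-99, miR-100 and miR-125, miR-10, miR-130 and miR-301 and miR-183 groups, squamous, carcinoma, pluripotency, hypoxia and NF-kB associated miRNAs, the DLK1-DIO3 and C19MC clusters, markers of mesenchymal, blood, endothelial, liver, muscle and neural cells, and RNA fragments listed as miRNAs. Each miRNA entered a list by its more abundant arm. The median of a list with at least 3 measured members was ranked among 10000 random lists of the same size, matched on mean level in 5 bins. The miRNAs named were chosen by a rule set before the data were examined: the 5 most abundant of each library, the 10 highest and 10 lowest log2 folds at a mean of at least 100 rescaled RPKM, and up to 4 members of each list. miR-98-5p, let-7g-5p, let-7b-5p, miR-429, miR-195-5p, miR-424-5p, miR-18a-3p and those outside the rule in the closing section were chosen after their values were seen.

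The steps were tested on simulated data: reads for all 2038 names drawn from the parental profile at the estimated depths, 200 of them changed 4-fold and the 20 most abundant kept constant. All 30 raised miRNAs past the filter were recovered, as were 23 of 25 lowered ones, and 2 of 202 unchanged ones were called. The simulation covers counting noise and does not test the scaling, since changes in the most abundant miRNAs would shift the total. In the real libraries some abundant miRNAs did differ, such as miR-203a. Alternatives were an unweighted trimmed mean of M values, median of ratios, upper quartile, a total without the most abundant miRNAs, a prior of 5, other filters, intervals beyond 2-fold and summed arms. RPKM as deposited was added after seeing the data. Gene neighbours came from RefSeq on GRCh38.p14 and hairpin sequences from GENCODE release 29. Both are on another build than the files, so no coordinates are given. Of the 269 measured miRNAs, 223 matched a gene and a hairpin by name. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.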

Results

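Mature miRNAs were profiled in FaDu head and neck squamous carcinoma cells grown as a parental culture and as spheres in serum-free stem cell medium, in order to find miRNAs that differ in the sphere-derived cells. There was 1 library per group, so no value below has a replicate check. Of 2038 miRNA names, 903 were above 0 in the parental library and 672 in the sphere library. Both libraries shared 603 of these names, while 300 were above 0 only in the parental library and 69 only in the sphere library. An estimated 4542489 reads lay on miRNAs in the parental library and 682359 in the sphere library, so low miRNAs are less precise in the spheres.

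The 2 libraries were dominated by the same few miRNAs. miR-21-5p, an abundant miRNA of carcinomas, had 187987 rescaled RPKM in parental cells and 258655 in spheres. let-7a-5p had 243075 and 179230, and let-7f-5p 134348 and 102810. The 5 most abundant miRNAs took 64.7% of the miRNA signal in the parental library (95% interval 64.6% to 64.7%) and 60.8% in the sphere library (60.7% to 61.0%). The parental group was completed by miR-92a-3p and let-7i-5p, and the sphere group by miR-203a and miR-22-3p. Across the 269 measured miRNAs the libraries had a Pearson r of 0.89 on the log2 scale and a Spearman rho of 0.87. These are correlations across miRNAs, which are not independent replicates.

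miRNAs made up a much smaller part of the reads behind the RPKM in the sphere library. Which reads the authors counted there is not stated. At 22 nt per miRNA, miRNAs accounted for 58.4% of the reads that the authors' RPKM refers to in parental cells and 12.1% in spheres. Lengths of 21 to 23 nt would give 55.7% to 61.0% and 11.6% to 12.7%. RPKM as deposited was 4.82 times lower in total in the spheres, and the median log2 fold of the measured miRNAs on that scale was -2.25. After rescaling to the miRNA total the median was 0.02. The log2 folds below are relative to the miRNA total. On the deposited scale they lie 2.27 lower, less far for miRNAs near the floor in parental cells and further for those near the floor in spheres. Away from the floor, a miRNA with a rescaled log2 fold between 0 and 2.27 is therefore higher as a share of miRNA. It is lower per read behind the authors' RPKM.

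Of the 269 measured miRNAs, 62 were at least 2-fold higher in spheres, 51 were at least 2-fold lower, and 156 lay within 2-fold. Scaling to the upper quartile gave 51 higher and 68 lower. On the deposited scale the split was 17 higher and 214 lower. The whole counting interval lay beyond 2-fold for 45 of the higher and 17 of the lower miRNAs.

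**Figure D1:**
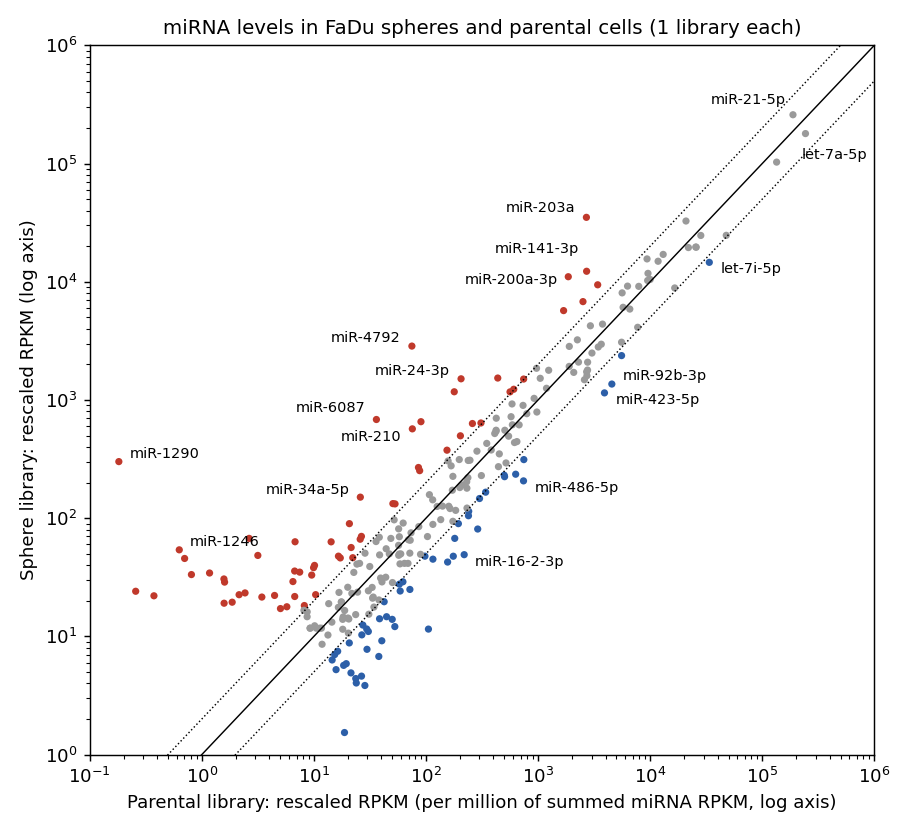
Rescaled RPKM of the 269 measured miRNAs in the parental (x axis) and sphere (y axis) library, both on log axes, 1 library each. The solid line marks equal values and the dotted lines 2-fold differences. Red points are the 62 miRNAs at least 2-fold higher in spheres and blue points the 51 at least 2-fold lower (17 and 214 on the deposited RPKM scale, which lowers the log2 folds by 2.27 except near the floor).

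Among abundant miRNAs, miR-203a stood out. This miRNA, which is abundant in differentiating stratified epithelium, went from 2698 to 35056 rescaled RPKM, a 13.0-fold difference (95% counting interval 12.7 to 13.3). It was also higher as deposited, at 71582 RPKM in parental cells and 193129 in spheres. miR-210, a target of the hypoxia factor HIF1A, was 7.50-fold higher (6.50 to 8.74). miR-24-3p was 7.33-fold higher (6.72 to 8.03), and miR-146b-5p, induced by NF-kB, 7.23-fold (6.34 to 8.32). miR-181c-5p was 6.55-fold higher (5.94 to 7.25), miR-200a-3p 5.93-fold (5.75 to 6.12) and miR-141-3p 4.52-fold (4.40 to 4.65). On the deposited scale only miR-203a of these stayed at least 2-fold higher, with a log2 fold of 1.43. miR-210 (0.65), miR-24-3p (0.61), miR-146b-5p (0.59), miR-181c-5p (0.45), miR-200a-3p (0.30) and miR-141-3p (-0.090) lay within 2-fold.

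Among the 129 miRNAs with a mean of at least 100 rescaled RPKM, the 3 highest folds belonged to miR-1290, miR-4792 and miR-6087. miR-4792 went from 74.8 to 2855 rescaled RPKM, a 37.9-fold difference (34.0 to 43.0), and miR-6087 from 36.1 to 683, or 18.7-fold (15.8 to 22.8). miR-1290 had less than 1 estimated read in the parental library and 205 in the sphere library. The lower bound of its fold was 257, and the upper bound 128630. These 3 were higher on the deposited scale too, by 8.28 (miR-1290), 2.99 (miR-4792) and 1.97 (miR-6087) in log2.

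Deficits in spheres were less extreme among these 129 miRNAs. miR-16-2-3p was 4.43-fold lower (3.16 to 6.50) and miR-671-3p 3.65-fold lower (2.59 to 5.40), on about 33 and 32 estimated sphere reads. miR-486-5p, abundant in erythroid cells, went from 741 to 207 rescaled RPKM and was 3.58-fold lower (3.03 to 4.28). miR-151a-5p was 3.56-fold lower (2.73 to 4.77). Both arms of the miR-423 hairpin were lower, miR-423-5p by 3.41-fold (3.17 to 3.67) and miR-423-3p by 2.34-fold (2.23 to 2.47). miR-92b-3p was 3.34-fold lower (3.13 to 3.57). The remaining 3 of the 10 largest deficits at this level were miR-548k at 2.68-fold lower, miR-125b-1-3p at 2.66-fold lower and let-7a-3p at 2.38-fold lower. These deficits were larger on the deposited scale. Among them, miR-16-2-3p, miR-151a-5p, miR-423-5p, miR-125b-1-3p and let-7a-3p are the less abundant arms. For miR-423 the more abundant arm, miR-423-3p, was at least 2-fold lower too. The more abundant arms of the others lay within 2-fold after rescaling, though not as deposited. Their log2 folds were -0.16 (miR-16-5p), -0.44 (let-7a-5p), -0.77 (miR-151a-3p) and -0.14 (miR-125b-5p). The last 2 of these were chosen after their values were seen. Below a mean of 100, miR-3615 (9.45-fold) and miR-25-5p (8.79-fold), chosen after their values were seen, were lower still, on about 1 and 8 estimated sphere reads. Unlike miR-125b-1-3p, miR-125b-2-3p was 4.31-fold higher (2.94 to 6.61), on 43 estimated sphere reads, and at -0.12 in log2 as deposited. It was also chosen after its value was seen.

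Epithelial miRNAs differed within their families. Of the 5 members of the miR-200 family, which represses the ZEB transcription factors, 2 were higher and none was at least 2-fold lower. The higher ones were miR-200a-3p and miR-141-3p, which share a seed. miR-200c-3p had a log2 fold of 0.66 and miR-429 of 0.37, while miR-200b-3p had -0.30. On the deposited scale only miR-200a-3p of the 5 was above 0. The family median of 0.66 lay at the 89.1 percentile of random lists. Of 3 squamous epithelial miRNAs, miR-203a was higher, while miR-31-5p had a log2 fold of 0.73 and miR-205-5p of -0.17 (-1.53 and -2.44 as deposited). In the mesenchymal list, 2 of 6 members were measured. miR-10b-5p had a log2 fold of -0.28 and miR-143-3p of 1.34, the latter on 45 estimated sphere reads and negative, at -0.91, as deposited.

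The let-7 family, whose members increase as progenitor cells differentiate, was measured with all 9 members. Only let-7i-5p passed the 2-fold rule, at 2.31-fold lower (2.26 to 2.36). The trimmed mean, median of ratios and upper quartile made it 2 of 9, with miR-98-5p, and on the deposited scale all 9 were lower. miR-98-5p had a log2 fold of -0.85, let-7a-5p -0.44, let-7f-5p -0.39 and let-7c -0.20. let-7g-5p and let-7b-5p were above 0, at 0.21 and 0.52 (-2.06 and -1.75 as deposited). The median was -0.39, at the 6.34 percentile of random lists. The let-7 members differ by few bases, so the division of reads among them is uncertain.

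**Figure D2:**
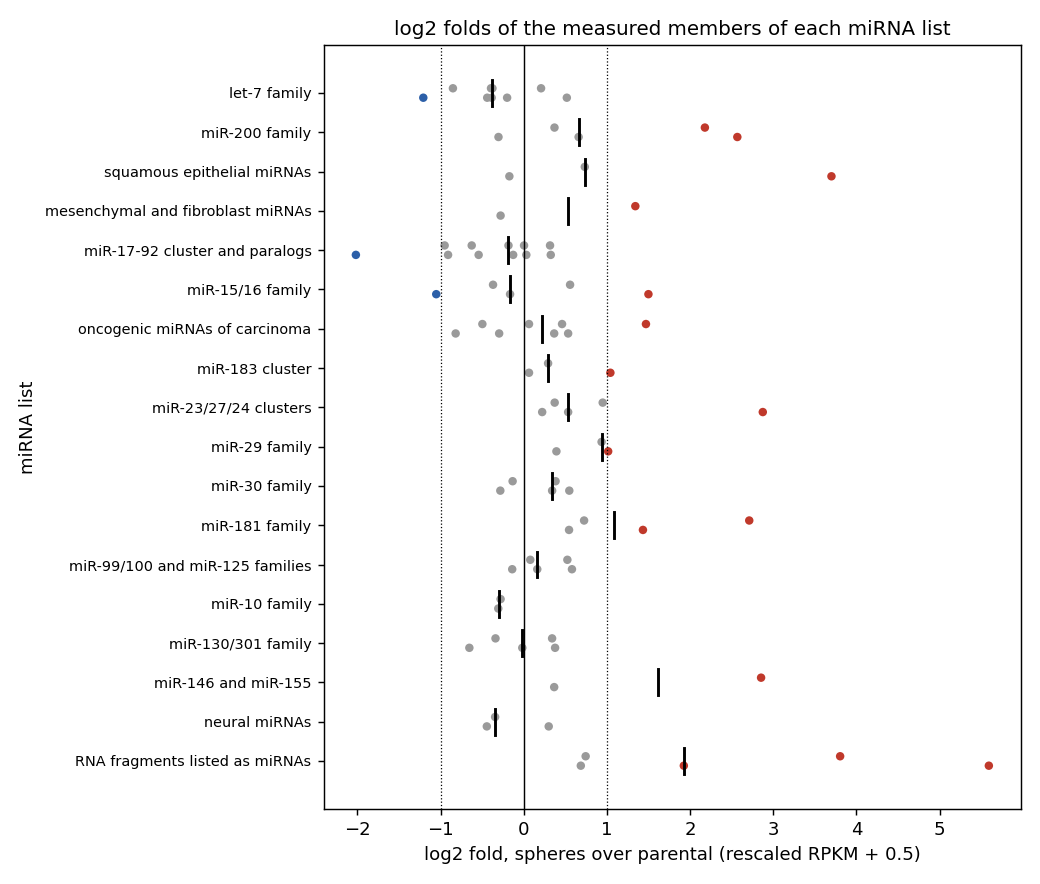
log2 fold (rescaled RPKM + 0.5, spheres over parental, 1 library each) of every measured member of each miRNA list with at least 2 measured members. Points are miRNAs, red at least 2-fold higher and blue at least 2-fold lower in spheres, and black bars are list medians. On the deposited RPKM scale points lie 2.27 further left except near the floor, and all 10 positive medians of lists with at least 3 measured members, like those of the smaller lists, fall below 0.

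No member of the pluripotency clusters of miR-302 and miR-371 was measured. The highest value there was 3.22 rescaled RPKM, for miR-371a-5p in spheres, against a floor of 4.40 for 3 reads. Of 11 measured members of miR-17-92 and its paralogs, which are driven by MYC, 1 was lower and none higher. The lower one was miR-18a-3p, chosen after its value was seen, with about 3 sphere reads. Under each of the 4 alternative scalings, 3 of 11 were lower, with miR-92a-3p and miR-25-3p added, and on the deposited scale all 11. miR-92a-3p had a log2 fold of -0.95, miR-25-3p -0.91, miR-93-5p -0.63 and miR-106b-3p -0.54. miR-106b-3p and miR-18a-3p entered as the more abundant arms. Their opposite arms, looked up after the values were seen, had -0.14 (miR-106b-5p) and -1.07 (miR-18a-5p). The list median of -0.18 lay at the 22.1 percentile. In the p53-responsive miR-34 family only miR-34a-5p was measured. It went from 25.9 to 151 rescaled RPKM, 5.71-fold higher (4.41 to 7.62), and had a log2 fold of 0.27 as deposited. Of 5 measured members of the miR-15/16 list, a family that targets cyclins, miR-195-5p was higher (2.83-fold), with a negative log2 fold of -0.74 as deposited. miR-424-3p was lower (2.07-fold). It entered as the more abundant arm but lacks the seed of the family, and miR-424-5p, which has it, had a log2 fold of -0.81. On the deposited scale 4 of the 5 were lower. miR-16-5p was at -0.16.

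The miR-181 family had the highest median of the miRNA families with at least 3 measured members, 1.08 at the 95.0 percentile of random lists, and -1.19 on the deposited scale. Of its 4 members, miR-181c-5p and miR-181a-5p were at least 2-fold higher (6.55-fold and 2.70-fold). miR-181b-5p and miR-181d had log2 folds of 0.54 and 0.73. In the miR-29 family, which targets collagens, 1 of 3 was higher, miR-29c-3p at 2.02-fold (1.88 to 2.17), a call lost under all 4 alternative scalings (log2 folds of 0.69 to 0.92). miR-29a-3p had 0.94 and miR-29b-3p 0.39, and all 3 were negative as deposited. Of the 5 miR-23/27/24 members only miR-24-3p was at least 2-fold higher. miR-27a-3p was at 0.53, miR-23a-3p at 0.37 and miR-27b-3p at 0.22, all negative as deposited. Of 3 members of the miR-183 cluster, miR-96-5p was 2.06-fold higher (1.35 to 3.13), at -1.21 in log2 as deposited, beside miR-182-5p at 0.06 and miR-183-5p at 0.29. The call of miR-96-5p was lost under all 4 alternative scalings (log2 folds of 0.72 to 0.95). None of 5 miR-30, 5 miR-99, miR-100 and miR-125, 2 miR-10 or 5 miR-130 and miR-301 members reached 2-fold in either direction, while all of them were at least 2-fold lower as deposited. Their medians were 0.34, 0.16, -0.29 and -0.02.

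Of 8 measured miRNAs often high in carcinoma, miR-221-3p was 2.77-fold higher (2.69 to 2.85), at -0.80 in log2 as deposited, and none was at least 2-fold lower, against 1 under 3 of the 4 alternative scalings and 7 as deposited. miR-21-5p was at 0.46 and -1.81 as deposited. In the NF-kB list, miR-146b-5p was higher, miR-155-5p had a log2 fold of 0.37 (-1.90 as deposited), and miR-146a-5p had about 10 and 9 reads.

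Markers of other cell types were mostly below the level counted as measured. The measured ones were not near the floor. For example, miR-126-5p had 154 rescaled RPKM in parental cells and 376 in spheres, and the neural miR-9-5p 348 and 429. miR-122-5p, the main miRNA of liver, was listed at 0 in both libraries. No muscle miRNA was measured. Of the blood cell miRNAs only miR-486-5p was measured, while miR-150-5p was listed at 0 in parental cells and at 13.2 rescaled RPKM in spheres, on about 9 reads. The endothelial miR-126-5p was 2.44-fold higher (2.11 to 2.82), at -0.98 in log2 as deposited and 0.96 with the upper quartile. None of 3 measured neural miRNAs reached 2-fold, while all 3 were lower as deposited. No member of the imprinted DLK1-DIO3 cluster was measured. In the placental C19MC cluster 1 of 35 was measured, miR-516a-5p, which was 13.4-fold higher (8.01 to 30.7) on 14 and 33 estimated reads. Of 5 measured RNA fragments listed as miRNAs, 3 were higher and none lower. miR-1246 was 48.2-fold higher (26.5 to 459) on 3 and 37 estimated reads, and miR-4454 3.80-fold (2.35 to 6.46). The list median was 1.92, at the 96.5 percentile of random lists, and -0.29 on the deposited scale. None of the 15 lists with at least 3 measured members had a median outside the central 95% of random lists. When low miRNAs were not filtered out, 6 lists did. These 6 are not counted out of the same 15, since further lists then have at least 3 members, some on few reads.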

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

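RPKM as deposited, an alternative added after seeing the data, changed the log2 folds and list medians most. It gave 17 higher and 214 lower miRNAs in place of 62 and 51, and all 17 were among the 62. Of the 2-fold calls of named miRNAs, 12 ended and 2 reversed, those of miR-96-5p and miR-29c-3p. Another 45 named miRNAs gained a call, all as lower. The log2 folds turned negative for miR-141-3p (-0.090), miR-143-3p (-0.91), miR-221-3p (-0.80), miR-96-5p (-1.21), miR-29c-3p (-1.25), miR-181a-5p (-0.83), miR-126-5p (-0.98), miR-195-5p (-0.74) and miR-4454 (-0.29). All 10 positive medians of lists with at least 3 measured members turned negative, to between -2.11 and -0.29, among them those above 1, the miR-181 family (-1.19) and the RNA fragments (-0.29). The cause lies in its construction, since the miRNA share of the reads behind the RPKM differs between the libraries. With no filter, 193 miRNAs were higher and 180 lower and 6 lists lay outside the central 95% of random lists, against 0 of 15 with it. These 6 are not counted out of the same 15, since further lists then have at least 3 members. At a mean of at least 100 rescaled RPKM, 129 miRNAs were left, 23 higher and 18 lower. Asking that the whole counting interval lie beyond 2-fold left 17 lower miRNAs, while 45 were higher. Fewer pass by construction, and the smaller number of sphere reads limits these intervals. The trimmed mean and the median of ratios each gave 55 higher and 65 lower. The upper quartile gave 51 and 68, the total without the most abundant miRNAs 56 and 56, and a prior of 5 59 and 42. Summed arms gave 59 and 36 among 223 summed names, in place of 269 miRNAs. The 4 alternative scalings moved the log2 folds by -0.20, -0.21, -0.32 and -0.10, so values between 0 and 0.32 have no firm sign even under these. On the deposited scale larger values turned negative as well, as listed above. None of the 4 alternative scalings reversed a 2-fold call of a named miRNA. All 4 ended the calls of miR-96-5p and miR-29c-3p and made miR-92a-3p and miR-25-3p at least 2-fold lower, and the upper quartile also ended the call of miR-126-5p (0.96). Summing repeated names could not be run, since no name is repeated. No paired analysis was possible because there is 1 library per group. Leaving out a replicate was not possible for the same reason.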

Other observations

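The hairpin search and the GC test were planned before their results were seen, and the other tests of explanations were chosen afterwards. Of the 223 hairpins searched, 9 shared at least 16 bases with another annotated non-coding RNA, which says nothing of the mature part alone. Of these 9 miRNAs, 5 were at least 2-fold higher in spheres, 1 was at least 2-fold lower and 3 lay within 2-fold. These miRNAs were chosen after their values were seen. miR-4485, which matches mitochondrial 16S rRNA, had a log2 fold of 3.91, miR-4284, matching a mitochondrial tRNA, 3.02, miR-3651, matching the snoRNA SNORA84, 2.15, and miR-664a-3p, matching SNORA36B, 1.55. miR-1246 (5.59) matched a U2 snRNA copy. miR-1304-3p (-1.64) was the lower one, and miR-301b (-0.65), miR-30b-5p (-0.28) and miR-15a-5p (0.56) lay within 2-fold. On the deposited scale miR-4485, miR-4284 (0.99) and miR-1246 (4.11) stayed above 0, while miR-3651 (-0.04) and miR-664a-3p (-0.63) did not.

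Neighbouring miRNAs had closer folds than random pairs. In 15 clusters of genes within 10 kb, limited to miRNAs with a mean of at least 100 rescaled RPKM, the median difference in log2 fold between members was 0.61, against 0.96 for random pairs, at the 2.72 percentile. In 6 clusters the members spanned 1 or more. Among these, miR-15b-5p and miR-16-2-3p, the less abundant arm, spanned 1.78. With miR-16-5p, which is made from several loci, in its place the span was 0.20. The limit leaves out measured miRNAs such as miR-18a-3p (-2.02) and miR-96-5p (1.04), so the spans hold only within it. These clusters also left out miRNAs made from several loci. With such miRNAs placed at each locus under the same limit, 26 clusters had a median difference of 0.62, at the 0.69 percentile of random pairs, and 9 clusters spanned 1 or more. The same values then enter several clusters, as for let-7a-5p and the repeated pair of miR-181a-5p and miR-181b-5p. Among the wide clusters, miR-24-3p and the pair of miR-92a-3p and miR-19b-3p recur. These clusters are not independent, so the lower percentile adds no support to the first. miR-221-3p exceeded its neighbour miR-222-3p by 1.77 (95% counting interval 1.68 to 1.85), miR-181c-5p exceeded miR-181d by 1.99 (1.79 to 2.19), and miR-660-5p (1.64) and miR-500a-3p (-0.38) of the X-linked cluster lay apart. miR-24-3p, one of those made from several loci, exceeded its neighbour miR-23a-3p by 2.50 (2.27 to 2.74). The paralogs miR-103a-3p and miR-107, which are near-identical in sequence, had log2 folds of 1.75 and 1.81. Whether minor arms fell behind major arms in spheres stays open. In 50 hairpins with both arms measured the major arm exceeded the minor one by a median of 0.50, at the 90.9 percentile of random pairs matched on level, and in 34 hairpins it lay above it. At least 2-fold lower were 14 minor and 8 major arms, and at least 2-fold higher 3 minor and 9 major arms.

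The first pattern is that miR-200a-3p and miR-141-3p were higher while their cluster mates were not. miR-200a-3p exceeded miR-200b-3p by 2.87 in log2 fold, and the lower counting bound of 2.74 argues against counting error. Higher output of the whole hairpins, with both arms raised alike, is argued against by the opposite arms. miR-200a-3p exceeded miR-200a-5p (about 34 sphere reads) by 2.49 and miR-141-3p exceeded miR-141-5p by 2.88, with the smaller lower bound at 1.96. Arms also parted in other hairpins, with major minus minor at 2.23 for miR-25 and -1.76 for miR-1307. Since a lag of minor arms in spheres stays open, higher output combined with such a lag is not excluded. An exchange of reads between the 2 miRNAs keeps their sum, so alone it could not place both above every cluster mate. Both exceeded the highest mate, miR-200c-3p, with 1.39 as the smaller lower bound of the difference, which argues against an exchange as the cause of both excesses. After removing a trend on hairpin GC the difference from miR-200b-3p was 2.97. The trend was 0.22 in log2 fold per 10 percentage points, and hairpin GC was 55.6% for miR-200a and 60% for miR-200b. So slight a trend could not have removed the difference, and the GC of the mature sequences was not available. GC bias therefore stays open. Reads of one of the 2 given to the other as the cause of one excess, the bias of adapter ligation or size selection between 2 single libraries, and a change in processing or stability of these arms in spheres, may each remain and were not tested.

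The second pattern is the fall of the miRNA share of the reads behind the authors' RPKM from 58.4% to 12.1%. Loss of a few abundant miRNAs is argued against, since the other measured miRNAs had a median log2 fold of -2.24 as deposited. Dilution by other RNA fragments may be a cause and cannot be told apart here. The part that is not miRNA grew by 1.08 in log2, while the fragment list had a median of -0.29 as deposited, with miR-1246 at 4.11 and miR-1260b at -1.57, so its members went both ways. A lower miRNA content of sphere cells, another size cut and RNA quality are all confounded with the single library per group.

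The third pattern is the excess of miR-1290, miR-4792 and miR-6087. A candidate explanation is that their reads come from longer RNAs. Of the 3 hairpins, 0 shared 16 bases with an annotated small RNA, but the reference holds no 18S or 28S rRNA transcript, so this stays open. A general rise of miRNAs numbered above 1000 is open as well. The other 41 had a median log2 fold of 0.72 (95% bootstrap interval -0.36 to 2.08) and of -1.51 as deposited. After rescaling, 19 of them were at least 2-fold higher and 10 at least 2-fold lower. The 3 lay above that interval, at 8.79 (miR-1290), 5.24 (miR-4792) and 4.22 (miR-6087). They were picked as the highest folds at a mean of at least 100, so this cannot decide the question.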
